A study of Homo sapiens with 6 samples.

How the data were processed

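RNA from HEK293T cells, a transformed human embryonic kidney line, was sequenced in 6 libraries: 3 from cells that received a guide RNA against SVA_D and 3 from cells without that guide. Per the labels, all 6 carried dCas9-VP64 with rtTA, and all 6 titles name SunTag; how the activator was joined to dCas9 is not stated. Per the labels' protocols, total RNA was extracted with TRIzol, copied to cDNA, amplified, size-selected and sequenced as read pairs on an Illumina NovaSeq. Nothing in the labels says whether the 3 replicates of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

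Per the submitters' processing notes, the tools were FastQC 0.11.8, STAR 2.7.0e and featureCounts 2.0.0 on the human builds GRCh38 and hg38. The deposited files hold raw counts, and 3 count tables exist for each library. Per the file headers, the gene counts were made without strand, for read pairs, over whole gene bodies of the protein-coding genes of Ensembl release 97, so intronic pairs count and pairs that overlap 2 genes or align to several places do not. Near-identical paralogs therefore lose counts, and reads of a gene and of an antisense partner cannot be told apart. Per the file headers, the subfamily counts add up repeat annotations over the genome with multi-mapping pairs included at each of their alignments. The SVA_D copy counts, per the file headers, were made in the same way for each genomic SVA_D copy. A read pair from one copy can thus be counted at several similar copies, and the count of a copy can exceed what came from it.

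The gene table holds 19986 genes, the subfamily counts cover 1180 repeat subfamilies and the copy counts cover 1546 SVA_D copies, of which 1454 lie on chromosomes 1 to 22, X and Y. Gene symbols were found for 19887 identifiers in a symbol table and for 93 more in GENCODE release 29, and 6 stayed as identifiers. Coordinates are those of the deposited tables (GRCh38). Intron and exon positions and non-coding genes came from GENCODE release 29, also on GRCh38.

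Gene totals ran from 16557854 to 22651168 counts per library and subfamily totals from 1292769 to 1699189. SVA_D copy totals were only 2608 to 4553 counts, so most copies had too few counts for a test. A floor of 3 counts corresponded to 0.128 to 0.187 CPM (gene counts scaled to 1e+06), depending on the library. Ratios of summed counts were given with exact 95% binomial intervals. Without molecular identifiers, such intervals and floors cover counting error only.

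Differences were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) on the raw counts, after filterByExpr with its default minimum count of 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Library sizes scaled by TMM came from the gene table and were used for all 3 tables, because a rise shared by the targeted repeats would be removed by scaling on the repeats. CPM values use these library sizes. Log2 fold changes are guide over no guide with their standard error (SE). Lists of genes and subfamilies written before the data were examined (25 gene lists, of which 1 holds all genes named ZNF and a number, and 14 lists of subfamilies) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Genes with a start site within 50 kb of an SVA_D copy were tested as a list in the same way. Summed values were compared with two-sided exact permutation tests, whose smallest p for 3 against 3 libraries is 0.1.

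The genes named in the text follow a rule fixed before the data were examined. With 5 or more genes past the threshold, it would have taken the 12 largest and 12 smallest changes. As fewer passed, it took the 5 smallest p-values on each side as genes that did not pass. It also took the 2 members of each list with the smallest p, and always ZNF91, ZNF611 and TRIM28. Of the list members named in this way, 1 is not reported here. For repeats it took SVA_A to SVA_F and up to 8 called subfamilies on each side. For SVA_D copies it took the 10 largest called changes, the 5 largest rises in CPM and up to 5 called copies that were lower. Genes beside the called copies were looked up after those copies were known.

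Replicate 3 of both groups stood apart. The alignment names in the file headers show another naming scheme and numbering for these 2 libraries, and the first principal component of the gene counts, which held 74.7% of the variance, separated them from the other 4. They are called batch B here and replicates 1 and 2 of both groups batch A. With the group in the model, 3530 genes were higher and 3454 lower in batch B among 13007 tested (edgeR). The main fits held no batch term, so this difference stayed in their spread between libraries. The common dispersion of the genes, edgeR's measure of that spread, was 0.0609 without the term and 0.00697 with it. The labels give both groups the same replicate numbers. Deviations of same-numbered libraries from their group means correlated at 0.51, 0.60 and 0.84 for replicates 1, 2 and 3, all over 0.1, so the numbers were taken to pair the libraries. This pairing follows the batches, and any pairing within batch A would have passed the bound of 0.1. Guide replicate 1 correlated at 0.568 with no-guide replicate 2 and at 0.511 with no-guide replicate 1. Guide replicate 2 correlated at 0.601 with no-guide replicate 1 and at 0.598 with no-guide replicate 2. The numbers thus have no support as pairs within batch A. Counts of replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 5.22, so no library was a copy of another of its group.

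Alternatives fixed in advance were library sizes from the subfamily table, from a joint table or without TMM, DESeq2 1.42.0, limma-voom, other filters, a minimum fold change, the replicate number as a block, leaving out each library, other windows, other set tests and a sum without the most counted copies. The batch as a covariate, each batch alone and the batch covariate without a count filter were chosen after seeing the data, as were the other windows with an estimated correlation. For batch B, with 1 library per group, 0.5 counts were added before taking a log2 ratio, and no test was made. The planned odds ratio for called genes near SVA_D copies had no called gene to use.

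The fits were tested on simulated counts made from the real means, batch difference and dispersions. These dispersions came from a model with the batch but not the group, so differences with the guide counted as spread. The simulated spread can thus exceed the real one, above all for the SVA_D copies. Among 13007 simulated genes, the model without a batch term called 1 of 67 genes changed 1.5-fold, 23 of 67 changed 2-fold and 47 of 66 changed 4-fold, and 0 of 12807 unchanged genes. With the batch term these were 49, 61, 65 and 12. Among 999 simulated subfamilies, it called 2 of 20 changed 1.5-fold, 13 of 20 changed 2-fold and 20 of 20 changed 4-fold without the batch term. Among 63 simulated SVA_D copies, it called 0 of 4 changed 2-fold, 1 of 4 changed 4-fold, 4 of 4 changed 16-fold and 1 of 51 unchanged copies. Figures were drawn with matplotlib 3.10.9.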

Results

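The series asked what a guide RNA aimed at a whole repeat subfamily does to the RNA of HEK293T cells. SVA elements are hominid-specific composite retrotransposons, and SVA_D is one of their 6 subfamilies (SVA_A to SVA_F). In CRISPR activation, a Cas9 protein that cannot cut brings an activator, here VP64, to the places its guide matches. The sample titles also name SunTag, a peptide array that recruits several activators. Total RNA was measured in 3 libraries with the SVA_D guide and 3 without it. The guide libraries held 20799011, 16557854 and 20701036 gene counts for replicates 1, 2 and 3, and the libraries without the guide held 22651168, 17318805 and 21360326. Replicate 3 of both groups formed a separate batch, called batch B, so values are also given for replicates 1 and 2 (batch A) and for the replicate 3 libraries alone.

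The first comparison was of the target subfamily and its relatives. SVA_D as a whole was at 177 ± 15.9 CPM with the guide and 149 ± 1.31 CPM without it (SD, n = 3 libraries each). The log2 fold change was 0.25 ± 0.13 (SE), which did not pass in the fit without a batch term (edgeR adjusted p = 0.999). It was 0.17 in batch A and 0.39 in batch B. SVA_E had the largest log2 fold change of the 6 subfamilies and was at 28.0 ± 2.79 CPM against 15.5 ± 0.288 CPM (SD, n = 3), a log2 fold change of 0.86 ± 0.14 (SE). Its edgeR adjusted p was 0.0646 over 999 subfamilies. With the replicate number as a block the adjusted p was 0.00383, with the batch as a covariate 2.95e-05, and with DESeq2 0.00107. Over 10 alternative settings it ran from 2.95e-05 to 0.189, with the log2 fold change between 0.78 and 0.92, and with 1 library left out from 0.0453 to 0.765. The SVA_E difference was 0.78 in batch A and 0.98 in batch B. SVA_F had a log2 fold change of 0.29 ± 0.13, SVA_C of 0.26 ± 0.15, SVA_A of 0.16 ± 0.14 and SVA_B of -0.012 ± 0.13 (SE), and none of these passed. SVA_B changed sign with the scaling, to 0.046 with library sizes from the subfamily table and 0.029 without TMM. Pairs that align to several places were counted at each, so part of the SVA_E counts can belong to SVA_D or other SVA subfamilies.

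**Figure D1:**
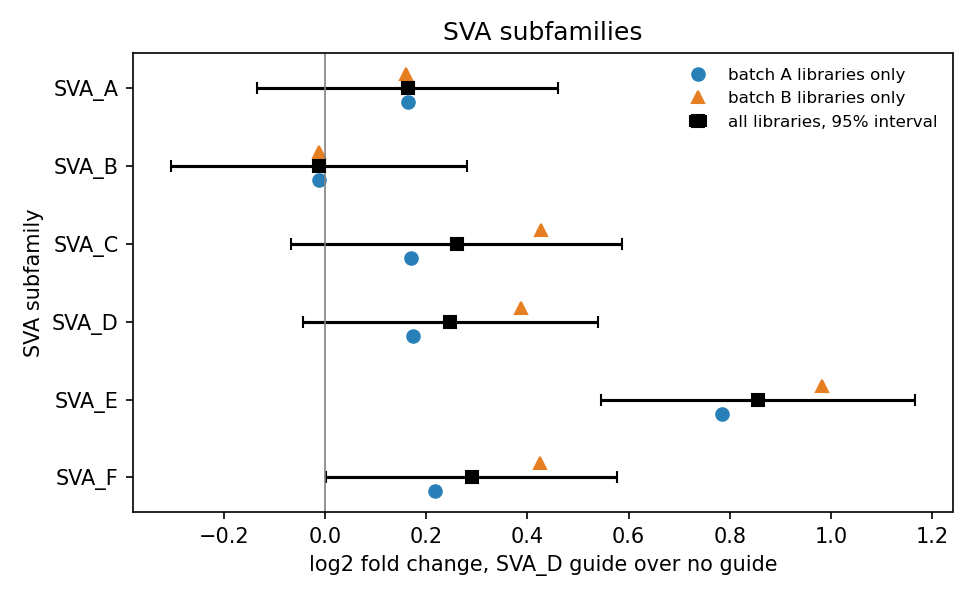
Log2 fold change of each SVA subfamily, guide over no guide. Squares with bars are the fit on all 6 libraries with its 95% interval, circles batch A and triangles batch B, which has 1 library per group. SVA_E lies at 0.86, SVA_D at 0.25 and SVA_B at -0.012.

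As a list, the 6 SVA subfamilies were higher than other repeats with the guide, with a median log2 fold change of 0.25 and 5 of 6 above 0 (camera adjusted p = 2.75e-07 over 14 lists). With an estimated correlation the adjusted p = 0.229, or 0.658 with the batch as a covariate as well. Adjusted over the list alone, 1 member passed (SVA_E), and over all subfamilies 0. With the batch as a covariate these counts were 4 (SVA_C, SVA_D, SVA_E and SVA_F) and 1. The median was 0.17 in batch A and 0.41 in batch B. No other repeat list passed. The medians were -0.12 for 24 AluY, -0.076 for 17 AluS and -0.072 for 8 AluJ subfamilies. They were -0.12 for 7 young L1, -0.13 for 19 older primate L1, -0.093 for 87 mammalian L1 and -0.055 for 8 L2 and MIR subfamilies. Among repeats of retroviral origin the medians were -0.018 for HERVH with LTR7, -0.014 for HERVK with LTR5, 0.038 for LTR12, -0.043 for MLT and THE1, and -0.040 for other internal HERV sequences. The 82 DNA transposons had a median of -0.063. All 999 subfamilies had a median of -0.058 on the scale of the gene counts. With library sizes from the subfamily table the Alu medians were -0.058, -0.013 and -0.010, and those of L2 with MIR, HERVH with LTR7, HERVK with LTR5, MLT with THE1 and other internal HERV sequences were above 0. The mean of the HERVK list was 0.039 and that of LTR12 -0.022, each opposite in sign to its median. Adjusted p-values of these 13 lists ran from 0.154 to 0.995, and the smallest was that of the older primate L1 list, which had an adjusted p of 0.0300 with the replicate number as a block and 0.0163 with library sizes from the subfamily table. For that list the adjusted p = 0.996 with an estimated correlation, 0.0516 with the batch as a covariate and 0.979 with both. Over all 999 subfamilies edgeR called 0 higher and 0 lower, with 4 higher and 8 lower at an unadjusted p under 0.05. The latter fall well short of a share of 0.05, as the batch difference stayed in the spread of this fit. With the batch as a covariate edgeR called 1 higher and 0 lower, with 16 higher and 21 lower at an unadjusted p under 0.05. DESeq2 called 1 (SVA_E) and limma-voom 0.

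The second comparison was of individual SVA_D copies. Of 63 copies with enough counts, 11 were higher with the guide and 0 lower (edgeR). DESeq2 and limma-voom each also called 11 higher and 0 lower. At an unadjusted p under 0.05, edgeR had 11 higher and 1 lower. All 11 were near the floor without the guide, with 1 to 14 counts summed over the 3 libraries, and had 36 to 120 counts with it. Each of the 11 was higher in every guide library of batch A than in both batch A libraries without the guide, and higher in batch B. Without guide replicate 3, 6 copies were called higher, and in batch A alone 8 of 62 tested.

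SVA_D_dup856 had the largest ratio. It lies on chromosome 10 from 97527497 to 97529792 in an intron of UBTD1, on the opposite strand, and had 106 counts with the guide against 1 without it. The ratio of these counts was 109, with a 95% counting interval from 19.1 to 4337. The level was 1.72 ± 0.631 CPM against 0.0143 ± 0.0247 CPM (SD, n = 3), and edgeR gave an adjusted p of 0.000427. SVA_D_dup1191, on chromosome 16 from 89462044 to 89463693 in an intron of the chromatin regulator gene ANKRD11 and opposite to it, had 85 counts against 2, a ratio of 43.6 (interval 11.7 to 366). SVA_D_dup28, on chromosome 1 from 26595456 to 26597516 outside annotated genes, had 36 counts against 2, a ratio of 18.5 (interval 4.76 to 158). Adjusted p-values were 0.000465 and 0.00303 for these copies (edgeR). SVA_D_dup28 did not pass without guide replicate 1 (adjusted p = 0.107) or without guide replicate 3 (0.0573).

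SVA_D_dup685, between genes on chromosome 8 from 141201549 to 141203194, was 10.5 times as high by counts (82 against 8, interval 5.09 to 25.2). SVA_D_dup149, on chromosome 2 from 3590120 to 3592244, lay 2588 bases from the start site of COLEC11. It rose from 0.206 ± 0.214 CPM to 1.95 ± 1.03 CPM (SD, n = 3), with 120 counts against 14, of which 71 came from guide replicate 3. SVA_D_dup377 on chromosome 4 from 76916101 to 76917314 had 94 counts against 11, of which 63 came from guide replicate 3, and did not pass in batch A alone (edgeR adjusted p = 0.0630) or without guide replicate 3 (0.0573). SVA_D_dup76 on chromosome 1 from 111607039 to 111608899 had 65 counts against 8 and did not pass without guide replicate 3 (edgeR adjusted p = 0.0573). It lies in an intron of RAP1A, opposite to it, and overlaps an exon of the non-coding gene LINC01160.

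SVA_D_dup862, in an intron of a non-coding gene on chromosome 10 from 114786699 to 114788346, had 56 counts against 8. It did not pass in batch A alone (edgeR adjusted p = 0.0662) or without guide replicate 3 (0.105). SVA_D_dup1216 on chromosome 17 from 17911652 to 17913237 had 59 against 9 and is the only one of the 11 in the same direction as a protein-coding gene that holds it, TOM1L2. SVA_D_dup1097 on chromosome 14 from 105078601 to 105080045 had 83 against 13, and SVA_D_dup802 on chromosome X from 126640734 to 126641971 had 36 against 6. SVA_D_dup802 did not pass in 5 of the 13 settings in which it was tested. Log2 fold changes of these 4 were 2.75 ± 0.71, 2.71 ± 0.53, 2.68 ± 0.68 and 2.57 ± 0.69 (SE). With 1 library left out they ran from 2.16 to 3.30, 2.43 to 3.15, 2.09 to 3.59 and 2.12 to 3.37. In the same fits SVA_D_dup856 ran from 5.80 to 8.07 and SVA_D_dup149 from 2.56 to 4.14. Since pairs that align to several places were counted at each, part of these counts can belong to other SVA copies.

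**Figure D2:**
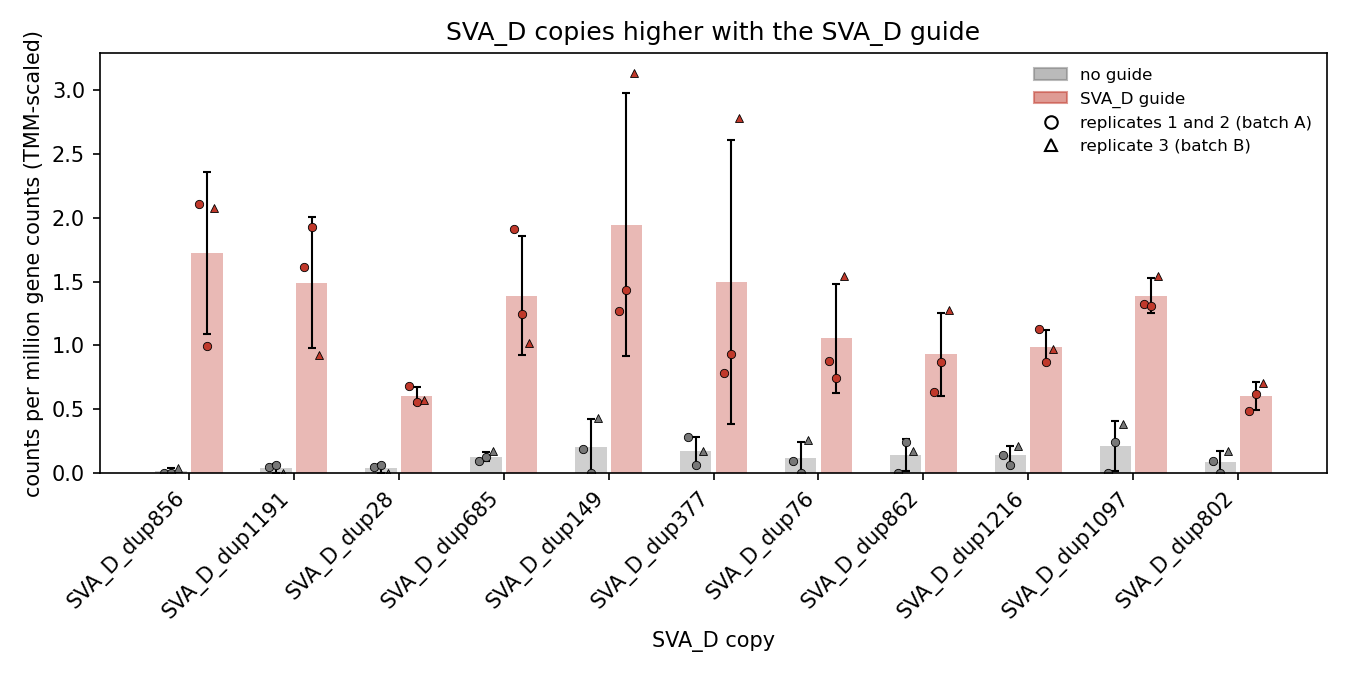
Level of the 11 called SVA_D copies in CPM of gene counts. Bars are means of 3 libraries, error bars 1 SD (drawn from 0 up) and symbols single libraries, with triangles for batch B. Guide libraries of SVA_D_dup149 reach from 1.27 to 3.13 CPM and those without the guide stay at or under 0.428 CPM.

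Summed over all 1546 copies, SVA_D stood at 185 ± 16.1 CPM with the guide and 157 ± 2.62 CPM without it (SD, n = 3), 1.18 times as high. Every guide library lay above every library without the guide, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. The log2 ratio was 0.16 in batch A and 0.38 in batch B. The 11 called copies together went from 1.29 to 13.6 CPM and made up 43.8% of the rise of 28.2 CPM, a share over copies chosen for being higher. Without these 11 the sum was 171 ± 14.4 CPM against 155 ± 3.20 CPM (SD, n = 3), with overlap between the groups (two-sided exact permutation p = 0.2). It was higher with the guide in 3 of 3 same-numbered pairs, by 0.349, 14.9 and 32.2 CPM. Within batch A this rests on the numbering, as guide replicate 1 (155.8 CPM) lay below no-guide replicate 2 (158.5 CPM). The 1483 copies with too few counts for a test made up 68.6% of the rise. These shares add up to more than the whole, as the other tested copies were lower in sum with the guide. The 11 called copies passed the count filter through their guide libraries. The 10 copies with the most counts, none of them among the 11, held 36.3% of the SVA_D counts without the guide and were at 55.7 CPM with it against 56.8 CPM without it.

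The third comparison was of protein-coding genes. Of 13007 tested genes, edgeR called 0 higher and 0 lower with the guide, and DESeq2 and limma-voom called 0. At unadjusted p under 0.05 edgeR had 19 higher and 4 lower, far short of the share of 0.05 that unchanged genes would give. With the batch difference in its spread, this fit gave p-values that were too large. Its 0 calls therefore do not show that no gene changed. The batch as a covariate also gave 0 and 0 (347 higher and 140 lower at unadjusted p under 0.05), and without a count filter that model called 5 higher and 2 lower, among the latter MT-ATP8. ZNF91, the zinc finger repressor that binds SVA elements, was at 6.67 ± 0.774 CPM with the guide and 7.31 ± 2.04 CPM without it (SD, n = 3). ZNF611, another SVA-binding zinc finger protein, was at 10.3 ± 3.82 CPM against 10.3 ± 1.35 CPM, and its log2 fold change turned to 0.018 without TMM. TRIM28, the co-repressor these proteins recruit, was at 500.3 ± 80.5 CPM against 480 ± 112 CPM. Their log2 fold changes were -0.13 ± 0.26, -0.010 ± 0.31 and 0.060 ± 0.21 (SE).

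The 5 genes with the smallest p among higher values, none of which passed, were XKR7, RAP1A, ZNF365, OR6J1 and ZAN. Their log2 fold changes were 1.40 ± 0.40, 0.96 ± 0.29, 0.96 ± 0.31, 1.47 ± 0.49 and 2.21 ± 0.77 (SE). With 1 library left out ZAN ran from 1.69 to 3.63 and OR6J1 from 0.90 to 1.74. OR6J1 encodes an olfactory receptor and ZAN the sperm protein zonadhesin. On the lower side they were GP1BA, a platelet adhesion receptor subunit, with -1.82, C2CD4A with -1.25, ANKRD50 with -0.29, the Wnt receptor gene FZD4 with -0.86 and WIPF3 with -0.43. Among these 10 genes, ANKRD50 was the most abundant, at 34.3 ± 1.24 CPM with the guide and 41.9 ± 1.38 CPM without it (SD, n = 3). The start sites of OR6J1 and RAP1A lie 6822 and 12127 bases from the nearest SVA_D copy. Those of the other genes lie at least 74936 bases away.

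RAP1A, which encodes a small GTPase of the Ras family, holds the called copy SVA_D_dup76 in an intron. The gene (ENSG00000116473) runs from 111542218 to 111716691 on the plus strand of chromosome 1 and overlaps TMIGD3 and INKA2 on the other strand. It was at 4.10 ± 0.392 CPM with the guide and 2.11 ± 0.424 CPM without it (SD, n = 3). The log2 fold change was 0.85 in batch A and 1.21 in batch B, and the difference did not pass by edgeR (adjusted p = 0.856 with the batch as a covariate). Pairs of the intronic copy that align to a single place count towards the gene, since gene counts cover introns without regard to strand, while pairs that align to several places count for the copy and not for the gene.

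**Figure D3:**
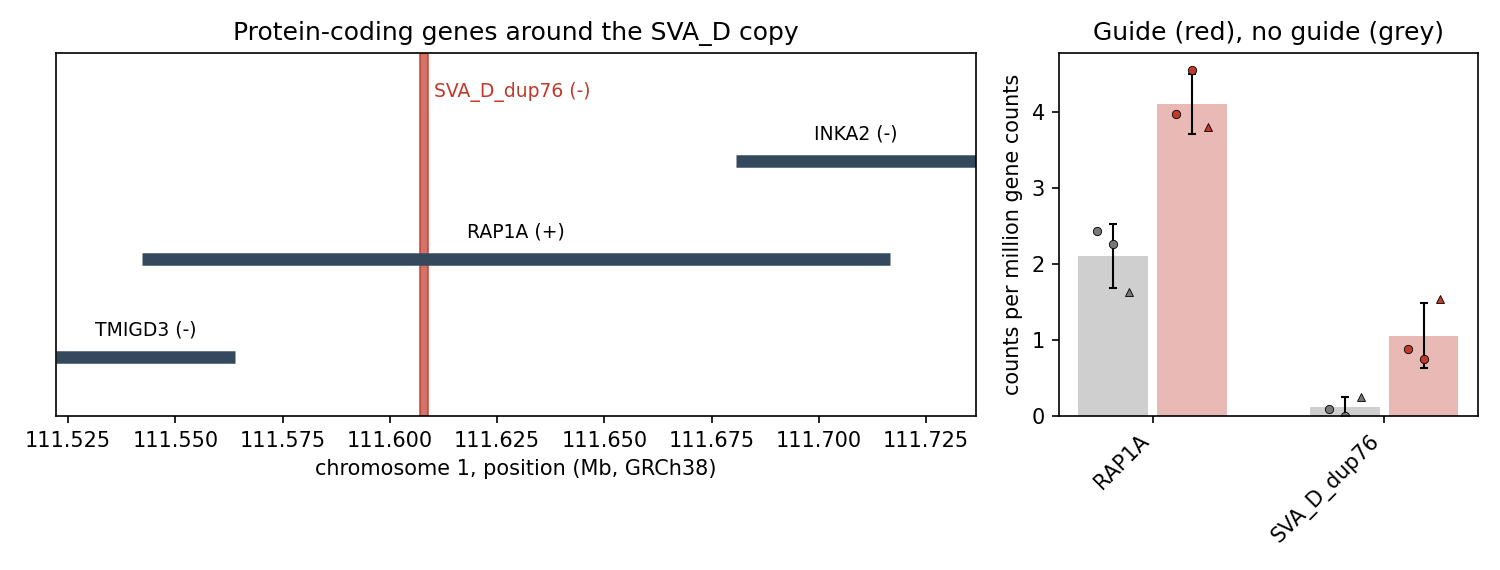
Left, protein-coding genes on chromosome 1 (position in Mb, GRCh38, strand in brackets) around SVA_D_dup76, marked as a red band. Right, CPM of RAP1A and for the copy, with bars for means of 3 libraries, error bars for 1 SD, circles for batch A and triangles for batch B. RAP1A lies at 4.10 CPM with the guide and 2.11 CPM without it.

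The other genes that hold a called copy differed by less than their standard errors: UBTD1 had a log2 fold change of 0.014 ± 0.38, ANKRD11 of 0.15 ± 0.17 and TOM1L2 of 0.12 ± 0.14 (SE). DENND3, the gene with the start site nearest to SVA_D_dup685, had 0.39 ± 0.18, COLEC11 0.28 ± 0.37, RPS6KA1 0.19 ± 0.29 and ABLIM1 0.052 ± 0.16 (SE). The 29 tested genes within 100 kb of the 11 copies ran from -0.27 to 0.96, with 21 above 0, among the others EXOSC1 at -0.13 and RPS7 at -0.16. None of these genes passed, and they were chosen after the copies were known.

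Genes near any SVA_D copy were then compared with the rest. The 1064 tested genes with a start site within 50 kb had a median log2 fold change of 0.017, against 0.0014 for the other 11943 genes, and this did not pass (camera p-value in limma, 0.170). Within 10 kb, 180 genes had a median of 0.031. The camera p-values for windows of 10, 100 and 500 kb were 0.0545, 0.225 and 0.0842. With an estimated correlation they were 0.0330, 0.0492, 0.0432 and 0.00061 for 10, 50, 100 and 500 kb, where at 50 kb the estimate was 0.0016 against the preset 0.01. The window of 500 kb held 6669 of the 13007 tested genes. Their median was 0.014 against -0.0086 for the rest, so its small p comes with a large set and a very small shift. With the count filter, no gene near an SVA_D copy was called, so no odds ratio for called genes could be computed.

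Of the 25 gene lists, 2 passed, both lower with the guide. All 13 tested mitochondrially encoded genes were below 0, with a median log2 fold change of -0.30 (camera adjusted p = 4.71e-12). With an estimated correlation the adjusted p = 0.996, or 0.581 with the batch as a covariate as well. MT-ND4, a complex I subunit, had -0.34 ± 0.17 and MT-ATP8, an ATP synthase subunit, -0.40 ± 0.21 (SE). Mitochondrial genes held 4.35% ± 0.471 of gene counts with the guide and 5.12% ± 0.362 without it (SD, n = 3, exact permutation p = 0.2), and the share was lower with the guide in 3 of 3 same-numbered pairs. Of 67 cytosolic ribosomal protein genes, 65 were below 0, with a median of -0.13 (camera adjusted p = 3.77e-07). Again the adjusted p = 0.996 with an estimated correlation, or 0.920 with the batch as a covariate as well. RPS24 had -0.20 ± 0.19 and RPL31 -0.21 ± 0.20 (SE). Neither held to the same size in both batches: the mitochondrial median was -0.39 in batch A and -0.029 in batch B, and the ribosomal median -0.24 and 0.093. Without no-guide replicate 1 the ribosomal median was 0.0060 (adjusted p = 0.442), and without guide replicate 3 the adjusted p = 0.193. Adjusted over the list alone, 0 members of any gene list passed, as over all genes. With the batch as a covariate, 8 mitochondrial genes passed over the list alone, among them MT-ND4L and MT-ATP8 (adjusted p = 0.00407 each), as did CORO1A (0.00206) of the haematopoietic list and CLDN4 (0.0365) of the epithelial list, and 0 passed over all genes. The start sites of CORO1A and CLDN4 lie 13122 and 1417 bases from the nearest SVA_D copy. Neither gene lies within 100 kb of the 11 called copies, and whether the nearby copies matter was not tested.

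Among immune and repeat defence lists, the 23 interferon response genes had a median of 0.12 with 21 above 0 (adjusted p = 0.324). The camera adjusted p = 0.000324 with the replicate number as a block and 0.00113 with the batch as a covariate. With an estimated correlation it was 0.996 without the batch and 0.581 with the batch as a covariate. Its median was 0.11 in batch A and 0.22 in batch B, and TRIM25 and the RNA sensor gene DHX58 had 0.12 ± 0.13 and 0.80 ± 0.99 (SE), with -0.0047 for DHX58 by limma-voom. With 1 library left out, which leaves the batches unequal between the groups, the interferon list was called up in 3 fits and down in 1. Under the 6 other settings its median stayed above 0, from 0.11 to 0.17. The repeat restriction list had a median of 0.079 (adjusted p = 0.0933), with 0.57 for PIWIL4 and 0.16 for the RNA-editing gene ADAR. The 35 genes of repeat-silencing chromatin had -0.0014 (adjusted p = 0.968), with ATF7IP at -0.14 and MORC3 at 0.16. The SVA-binding zinc finger list had -0.020 (adjusted p = 0.650) with ZNF28 at -0.056, and the 355 ZNF genes 0.0029 (adjusted p = 0.968) with ZNF442 at 0.75. The inflammatory list had -0.037 (adjusted p = 0.996), with NFKB2 at 0.27 and CXCL8 at 0.48, and the immediate early list -0.0051 (adjusted p = 0.968), with NR4A1 at 0.25 and NR4A2 at 0.26.

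Stress lists did not pass. The medians were 0.033 for the integrated stress response (adjusted p = 0.725), 0.020 for the unfolded protein response (adjusted p = 0.968), -0.024 for heat shock (adjusted p = 0.650), 0.051 for p53 targets (adjusted p = 0.624) and -0.068 for hypoxia and glycolysis (adjusted p = 0.0933). With the replicate number as a block, the hypoxia list had an adjusted p of 0.00695 (adjusted p = 0.996 with an estimated correlation, or 0.920 with the batch as a covariate as well). Their leading members were SESN2 at 0.23, ADM2 at 0.18, HSP90B1 at 0.31, HYOU1 at 0.28, DNAJB1 at -0.10, BAG3 at 0.11, PHLDA3 at 0.19, EGLN3 at -0.23 and P4HA2 at -0.16. Among growth lists, the medians were -0.032 for the mitotic list (adjusted p = 0.324), -0.011 for DNA replication (adjusted p = 0.968), 0.015 for replication histones (adjusted p = 0.968), 0.022 for ribosome biogenesis (adjusted p = 0.923) and -0.034 for cholesterol synthesis (adjusted p = 0.650). UBE2C had -0.18, TTK -0.13, CCNE2 -0.22, POLD1 0.11, H4C5 0.85, H2BC9 -0.64, NOP56 0.083, ODC1 0.083, LSS 0.18 and SC5D -0.18.

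Many markers of other cell types had too few counts for a test, and no such list passed. The haematopoietic list had 4 of 19 genes tested and a median of 0.26 (adjusted p = 0.0933, or 0.0129 with the replicate number as a block). For this list the adjusted p = 0.996 with an estimated correlation, 0.0639 with the batch as a covariate and 0.581 with both. With 1 library left out its median ran from -0.16 to 0.74, and it was called up in 3 of these 6 fits. The leukocyte actin regulator CORO1A had 1.19 ± 0.56 (SE). The epithelial list had 7 of 18 tested and a median of 0.21 (adjusted p = 0.0933), with CLDN4 at 1.05 and KRT17 at 0.59. Its median was -0.14 in batch A and 0.35 in batch B. With 1 library left out, which leaves the batches unequal, the epithelial median ran from -0.059 to 0.84. The list was called up in 5 of these 6 fits. The germline list had 7 of 35 tested and 0.36 (adjusted p = 0.0933), with HORMAD1 at 0.84 and MAGEA3 at 0.39. Fibroblast markers had 0.048 (adjusted p = 0.923), with PDGFRA at 0.27 and PRRX1 at 0.098. Neuronal markers had 0.012 (adjusted p = 0.996), with CHGB at 0.63 and CHGA at 0.37, and pluripotency markers 0.013 (adjusted p = 0.996), with UTF1 at 0.41 and LIN28B at -0.11. In 4 lists the median and mean differed in sign (immediate early, inflammatory, DNA replication and silencing chromatin), and in the histone and pluripotency lists both were above 0 while the test pointed down.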

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

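The batch as a covariate, each batch alone and the batch covariate without a count filter were chosen after seeing the data, as were the other windows with an estimated correlation. The count of called SVA_D copies stayed from 8 to 12 of those tested with all libraries or batch A alone, and ran from 6 without guide replicate 3 to 13 without no-guide replicate 3. A minimum of 10 counts in every library of a group called 1 copy lower, SVA_D_dup663. The SVA_D log2 fold change stayed above 0, from 0.17 to 0.31, with 0.39 in batch B, and the summed copies had 0.38 in batch B, where each group has 1 library.

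The number of subfamilies called higher was 1, SVA_E, with DESeq2, library totals without TMM, no count filter, the replicate block, the batch covariate and batch A alone, and 0 to 1 with 1 library left out. Of the repeat lists, 2 were called with sizes from the subfamily table and with the block (SVA and older primate L1), 0 with an estimated correlation, and 1 to 4 with 1 library left out. Of the gene lists, 5 were called with the block, 4 with the batch covariate, 0 with an estimated correlation, 0 with fry, and 3 to 10 with 1 library left out. For the ribosomal list the adjusted p ran from 3.57e-23 to 0.442 with 1 library left out, and was 0.996 with an estimated correlation and 0.991 with fry. The block changed no call other than those of SVA_E and the lists. Genes near SVA_D copies had a camera p with an estimated correlation of 0.0330, 0.0492, 0.0432 and 0.00061 for windows of 10, 50, 100 and 500 kb. The window of 500 kb held 6669 of the 13007 tested genes, with a median of 0.014 against -0.0086 for the rest. The batch covariate without a count filter called 5 genes higher and 2 lower. The odds ratio for called genes near SVA_D copies was not computed, as no gene was called with the count filter.

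SVA_B went to 0.046 with sizes from the subfamily table and 0.029 without TMM, DHX58 to -0.0047 with limma-voom and ZNF611 to 0.018 without TMM. The cause of these changes was not tested. With 1 library left out, log2 fold changes ran from -0.060 to 0.035 for SVA_B, -0.73 to 1.46 for DHX58, -0.23 to 0.27 for ZNF611, -0.12 to 0.25 for BAG3, -0.084 to 0.67 for HSP90B1, -0.043 to 0.63 for HYOU1, -0.27 to 0.20 for LIN28B, -0.019 to 0.42 for NFKB2, -0.026 to 0.15 for NOP56, -0.0010 to 0.17 for ODC1, -0.11 to 0.74 for PDGFRA, -0.12 to 0.18 for TRIM28, -0.18 to 0.82 for UTF1, -0.19 to 0.11 for ZNF28 and -0.25 to 0.12 for ZNF91. Leaving out a library leaves the batches unequal between the groups by construction.

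The changes of direction above leave out the lists that did not pass with all libraries, and the named genes under the alternatives added after seeing the data. Both were left out after many of them were seen to change sign. With 1 library left out, the median of 23 of 25 gene lists and 10 of 14 repeat lists took the other sign at least once, and 5 gene lists (interferon, unfolded protein, integrated stress, histones and ribosome biogenesis) were called up in some cases and down in others. Under the other settings 10 gene lists and 5 repeat lists took the other sign. Of 55 named genes with a value in both batches, 16 had opposite signs in batch A and batch B. Few counts limit the SVA_D copies: 1483 of 1546 were not tested.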

Other observations

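All tests in this part were chosen after the result was seen, except those of the length of the copies, of their place in genes and of protein-coding genes with few counts. The sum without the most counted copies was planned, and its use as a test was chosen after. With the batch as a covariate and no count filter, itself chosen after seeing the data, edgeR called 5 genes higher with the guide. They included the MHC class II gene HLA-DRB5 (log2 fold change 1.53, adjusted p = 0.00277), MYOF (1.34), ESAM, an endothelial adhesion molecule (1.16), and the leukocyte actin regulator CORO1A (1.14). CORO1A was at 5.25 ± 3.61 CPM with the guide and 2.30 ± 0.959 CPM without it (SD, n = 3), and without guide replicate 3 its log2 fold change was 0.46 in the fit without a batch term. That fit leaves the batches unequal, and the log2 fold change of CORO1A was 0.82 in batch A and 1.52 in batch B. The 2 genes called lower were MT-ND4L (-0.51) and MT-ATP8 (-0.40), both mitochondrially encoded. None of these 7 genes passed with the count filter. Guide replicate 3 had the highest value of the 4 named genes that were higher. The groups overlapped for each of the 7 over all 6 libraries, but not within batch A, and batch B went the same way. HLA-DRB5 was at 1.71 and 1.43 CPM against 0.334 and 0.672 CPM in batch A. MT-ND4L was at 1015 and 1195 CPM against 1390 and 1421 CPM there. The genes were chosen by a fit with the batch as a covariate, so this separation is not separate evidence.

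SVA_D copies with a count numbered 609 ± 84.2 per library with the guide and 503 ± 35.7 without it (SD, n = 3, two-sided exact permutation p = 0.1). A count in every guide library and in no library without the guide was found for 17 copies, and the reverse for 3. In all, 486 copies had no count in any library.

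The 11 SVA_D copies called higher were weighed against 3 technical explanations. A batch difference is argued against, since each group holds the same number of libraries of each batch and each of the 11 was higher within both batches. With the batch as a covariate 11 of 11 stayed past the threshold (edgeR). That adds little, as a covariate balanced between the groups could hardly move their fold changes. Transcription through a protein-coding host gene is argued against for 10 of the 11, of which 7 lie in no such gene and 3 in a gene whose 95% interval ends below that of the copy, the exception being SVA_D_dup76 in RAP1A. Among the 7, SVA_D_dup862 lies in a non-coding gene for which there are no counts, so its host stays open. Reads of a single transcript counted at several copies may account for part of the pattern: the proportions of the 11 copies gave a Monte Carlo permutation p = 0.355 between the guide libraries of batch A and p = 1e-05, the smallest the resampling can give, over all 3 guide libraries, but neither decides, as both set libraries against counting noise alone and count some pairs at several copies.

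Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called SVA_D copies, the real one with 11, and the highest of the others gave 1, but 10 splits are too few for a share under 0.05. Of the 4 splits that part all 3 same-numbered pairs, the 3 others called 0 copies, and the remaining 6 splits keep a pair together. For subfamilies, 10 of the 10 splits gave at least the real count of 0, and the highest other count was 272, from guide replicates 1 and 3 with no-guide replicate 3 against the rest. Such a count points to a structure of the samples. This split parts the libraries by their subfamily totals on the scale of the gene counts. The totals were 72844, 63690 and 63761 CPM for guide replicates 1 and 3 and no-guide replicate 3. They were 80439, 80972 and 81520 CPM for guide replicate 2 and no-guide replicates 1 and 2. Guide replicate 1 thus lay below the rest of batch A, which limits the subfamily comparisons on this scale. Whether the totals account for the whole count was not tested. Batch alone does not account for the count, as 4 splits put both batch B libraries on the same side and 3 of these called 0 subfamilies. For genes, 10 of 10 splits gave the real count of 0 and the highest other was 0. Every split reaches a count of 0, so neither comparison bears on chance.

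RAP1A stood 1.99 CPM higher with the guide, and its intronic copy SVA_D_dup76 stood 0.940 CPM higher. Subtracting the copy takes away too much of its own pairs, since those that align to several places were not counted in the gene. Even so, 1.05 ± 0.24 CPM (SE of 3 same-numbered pairs) were left, with 0.748, 1.53 and 0.881 CPM in pairs 1, 2 and 3, and an exact sign-flip p = 0.25, the smallest that 3 pairs allow. This argues against reads within the copy as the whole difference. However, pairs beside the copy from a transcript that overlaps it, such as LINC01160, would count for the gene and were not subtracted. The comparison by pairs was chosen after the one without pairs was seen, in which the SE was 0.54 and the groups overlap (two-sided exact permutation p = 0.3). As the numbers have no support as pairs within batch A, those libraries were also paired the other way, which gave an SE of 0.20. Reads of the copy may account for part of the difference. As RAP1A did not pass over all genes, chance, RNA from beside the copy and a change of the gene with the guide all stay open.

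Without the 10 most counted copies the summed log2 ratio was 0.37, against 0.24 for all copies, which followed from the level of these 10 (0.981 times as high with the guide) and decides nothing. A rise spread over copies with few counts is a candidate explanation for the sum: 749 copies with 1 to 9 counts over all libraries summed to 26.5 ± 6.40 CPM with the guide and 17.7 ± 1.36 CPM without it (SD, n = 3), 1.49 times as high, with 1.26 in batch A and 1.99 in batch B, and 480 of them were higher. Pairs of the called copies that align to several places can also count at these copies. Such pairs could raise the sum as well, and the 480 are not separate observations. Background reads over the whole genome stay open: 1971 protein-coding genes with 1 to 9 counts had a ratio of 1.097 ± 0.383 (SE), with 0.962 in batch A and 1.26 in batch B, so the bound of 1.1 set for excluding it was met by less than its spread. The condition on the spread was added after this value was seen.

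Longer copies may respond more, but the median length was 1648 bases for the 11 copies and 1526.5 bases for the other 52 tested copies, which did not separate them (two-sided permutation p = 0.288). Copies outside genes may have been easier to detect as changed, as 4 of the 11 and 29 of the other 52 lie in a protein-coding gene (Fisher's exact p = 0.325), and these counts are too few to decide. Copies may raise the genes around them: 29 tested genes within 100 kb of the 11 copies had a median log2 fold change of 0.050 with 21 above 0, at the 98.5th percentile of 10000 random lists matched on expression. Without the genes that hold a copy it was 97.3, in batch A 95.5 and in batch B 99.3. The random lists drew single genes over the whole genome, while the 29 genes lie in groups of neighbours, so the percentiles take linked genes as independent. Both batches had also served to choose the copies. A rise of genes around copies stays a hypothesis from the same data, and no single gene of the 29 passed.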
